A study of Mus musculus with 26 samples.

How the data were processed

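Genomic DNA of mouse uterus and decidua was profiled by methylated DNA immunoprecipitation sequencing (MeDIP-seq), and mRNA of uterine stromal cells (USC) by RNA-seq. Per the labels' protocols, sonicated DNA was enriched with an antibody against 5-methylcytosine and sequenced in read pairs. RNA libraries were made from selected mRNA with a strand-specific kit and sequenced from one end. MeDIP-seq measures enrichment relative to the rest of the library and gives no methylation percentage. Groups and replicate numbers were taken from the sample titles. Aged abnormal decidua replicate 1 was not analysed here.

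The USC table holds raw read counts per gene, as deposited by the authors and named so in the labels. The island and window tables hold log2 values deposited by the authors for each library. Their scale was worked out from the values: each is the log2 of a read number scaled to the largest library, per kb of island in the island table and with no length correction in the window tables. Undoing these steps gave whole reads for 100% of island values (relative tolerance 0.01), with islands of 0 reads entered as 0.9 read. Per the submitters' processing notes, Trim Galore 0.3.8 and 0.4.4, Bowtie2 2.3.2, TopHat2 2.0.12, DESeq2 and the build GRCm38 were used, with no role given to any of them. How reads were counted, how windows were selected and how the stromal cells were isolated is not given in the sources used here. Coordinates are those of the files, on GRCm38.

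The count table held 25965 genes, of which 9241 had 0 counts in all 6 libraries; 124 gene entries share a symbol with another. Aged and young USC were compared with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F-test, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and an FDR of 0.05. The replicate number was not used as a block. A fold against libraries that all held 0 counts is given as a lower bound against 3 counts over the group. A gene with 1 to 3 counts over a group is given as a ratio with a 95% counting interval. Both cover counting error only. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation. DESeq2 1.42.0 was the second tool. It left 10817 genes without an adjusted p.

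Islands were analysed with limma (intensity trend, empirical Bayes) on the deposited log2 values, all 5 MeDIP groups in one model. Islands with a mean of at least 5 recovered reads per library were tested, 6814 of 23070 (29.5%). This minimum was set after no minimum, 5 and 10 reads had been looked at. As a second tool, edgeR was run on the recovered reads, an alternative added after the data were seen. Islands and windows were assigned with bedtools 2.31.1 to genes of GENCODE vM21 that they overlap or lie within 2 kb upstream of. This gave 20588 islands (89.2%) a gene. The windows are the authors' selection, so no test of single windows was run. Mean signal over windows on both lists was compared with 2-sided exact permutation tests, and within litters with an exact sign-flip test. Overlap of the young and aged windows was set against 1000 shuffles within chromosomes. Tracts of alternating CA or TG of at least 16 bp were searched in and within 200 bp of windows and islands, and for windows also within 500 bp. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.

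In total, 25 gene lists were fixed before the data were examined. They cover decidualisation, Wnt signalling, TGF-beta and BMP signalling, extracellular matrix, contractile genes, proliferation, senescence, interferon response, cholesterol biosynthesis, hypoxia and glycolysis, immediate early and heat shock genes, DNA methylation, Polycomb complexes, imprinted genes, germline genes, Hox clusters, other developmental transcription factors, trophoblast genes, mitochondrially encoded transcripts, and markers of epithelial, endothelial, macrophage, lymphoid, mesothelial and erythroid cells. Of their 706 genes, 691 were found by symbol and 11 by identifier. The lists of imprinted, germline, Hox, developmental and decidualisation genes were also tested on islands. Lists of further endothelial, lymphatic endothelial and stromal identity genes were written after the USC result was seen. The comparisons, the main tests and most alternatives were also fixed before the data were examined.

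Genes were named by a rule fixed in advance. For USC these were the 10 largest rises and 10 largest falls among passing genes with no overlap between the ages and at least 2 CPM in the higher group, up to 3 passing genes per list and direction, and a fixed set of decidualisation and DNA methylation genes. For islands these were the 6 largest gains and losses with an assigned gene, up to 3 passing islands per list and direction, or, where fewer than 3 passed, the 3 smallest p-values per direction. For windows these were the 8 largest gains and losses in protein-coding genes, up to 10 windows in decidualisation genes and up to 4 for each other list. The rule ranked windows by the authors' fold and p-value; the window tables used here hold neither, so windows were ranked by the difference between the group means of their log2 values.

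USC libraries held 9028248 to 15688638 counts, at which 3 counts equal 0.191 to 0.332 CPM. MeDIP libraries held 85877 to 196652 reads in islands, a median of 1 to 3 reads per island, with 14.4% to 29.9% of islands at 0 reads. Replicates differed by more than counting noise in every USC pair (chi-square per degree of freedom 15.1 to 184). Island pairs ranged from 1.05 to 2.74, and the values near 1 cannot tell separate animals from repeats of one sample. Following the labels, no library was counted as a repeat of another. Aged normal and abnormal deciduae with the same number come from one litter per the labels. Their deviations from the group means correlated at 0.07 to 0.18 over the 4 pairs. Pairs of different litters reached 0.145, and only 1 of the 4 correlated best with its own litter, so these correlations do not bear out the pairing. In simulated data at the real depth, the USC step recovered 4%, 18%, 82% and 100% of genes changed 1.5-, 2-, 4- and 8-fold. In these data 50 genes were changed at each fold, far fewer than passed in the real comparison. Alternatives were other scalings, filters, tools and models, a replicate block, chromosomes X and Y left out, other gene assignments and each library left out in turn.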

Results

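The series compared reproductive tissue of young and aged C57BL/6 mice. MeDIP-seq, which enriches methylated DNA with an antibody, was done on 20 libraries. These came from uterus at embryonic day 3.5 (E3.5), from 3 young (8 to 20 weeks) and 5 aged (41 to 49 weeks) females, and from decidua, the transformed uterine lining around the embryo, at E11.5. The decidua libraries were 3 from young mothers (9 to 10 weeks), 5 from aged mothers (43 to 47 weeks) beside embryos of normal appearance, and 4 beside abnormal embryos of the same aged litters. The series' design text gives other numbers, 6 young and 10 aged deciduae with n = 3 for each aged class. The labels were followed, and the difference was not resolved. RNA-seq was done on uterine stromal cells (USC) of 3 young (10 weeks) and 3 aged (47 to 48 weeks) females. The labels call these biological replicates. Total counts per USC library ran from 9028248 (aged replicate 3) to 15688638 (young replicate 1). Reads in CpG islands ran from 85877 (aged uterus replicate 5) to 196652 (aged normal decidua replicate 3).

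The USC libraries addressed how gene expression in uterine stromal cells differs with the female's age. Most endothelial genes stood at high levels in aged USC and at or near 0 in young USC. Interferon response genes also rose, while most contractile, extracellular matrix, mesothelial and Wnt pathway genes fell. The hormone response genes Hand2, Esr1, Pgr and Hoxa11 fell as well. Since endothelial genes rose and most stromal identity genes fell, a change within stromal cells cannot be told apart from a difference in the cells sequenced. This holds for all USC differences given below. Of 12854 tested genes, 3382 (26.3%) passed an FDR of 0.05 in edgeR's quasi-likelihood test, 1578 rising and 1804 falling, and 3160 of them changed at least 2-fold. The ages did not overlap for 5637 tested genes (43.9%, against 10% by chance for 3 against 3 libraries). Values that follow are mean CPM ± SD with n = 3 per age. Of the 21 lists with at least 3 tested genes, 9 passed camera's test with the preset correlation, and only the endothelial and contractile lists passed it with an estimated correlation. Of the 10 splits of these libraries into 3 against 3, 6 gave at least 9 lists, the real one included, and the highest other gave 11. The number of passing lists therefore does not set age apart from other splits.

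Endothelial markers rose in 15 of 16 tested members (15 when adjusted over the list alone), with a median log2 change of 10.13, or 9.07 with the genes at 0 set to their bound. In camera the adjusted p was 5.02e-16, and 0.0314 with an estimated correlation. Tie1 (ENSMUSG00000033191, chromosome 4, 118471191 to 118490061), a receptor kinase of endothelium, had 1 count in the young libraries and 11610 in the aged, a ratio of 10280 (1845 to 406058, 95% counting interval). Erg, an endothelial transcription factor, had 1 count against 11197, a ratio of 9914 (1779 to 391615). Robo4, a vascular guidance receptor, stood at 0.105 ± 0.106 CPM in young and 246 ± 49.9 in aged USC (log2 change 10.86, and 11.86 without young replicate 1). Pecam1, the adhesion molecule of endothelial junctions, lay between 0 and 0.826 CPM in the young libraries and between 1134 and 1321 in the aged.

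Contractile and smooth muscle genes fell in 16 of 18 tested members (17 when adjusted over the list alone), with a median log2 change of −3.26. The list's adjusted p in camera was 3.36e-11, and 0.0314 with an estimated correlation. Myh11, the smooth muscle myosin heavy chain, fell from 454 ± 28.5 to 17.8 ± 3.71 CPM, and Cnn1, the actin-binding calponin, from 1057 ± 243 to 56.8 ± 8.94. Oxtr, the oxytocin receptor, fell from 24.0 ± 5.34 to 0.434 ± 0.0255 CPM. Interferon response genes rose in 29 of 32 tested members (31 when adjusted over the list alone), median log2 change 3.07. Camera's adjusted p was 1.22e-17, and the adjusted p = 0.0783 with an estimated correlation missed the threshold. Irf7, a transcription factor of the interferon response, rose from 13.5 ± 2.41 to 204 ± 40.0 CPM, the guanylate-binding protein gene Gbp3 from 3.85 ± 1.37 to 128 ± 11.1, and Rsad2, an antiviral enzyme, from 1.12 ± 0.461 to 40.0 ± 7.54. In the same libraries Cdh5, the endothelial cadherin, stood at 0 to 1.13 CPM in young and 1513 to 2009 in aged.

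**Figure D1:**
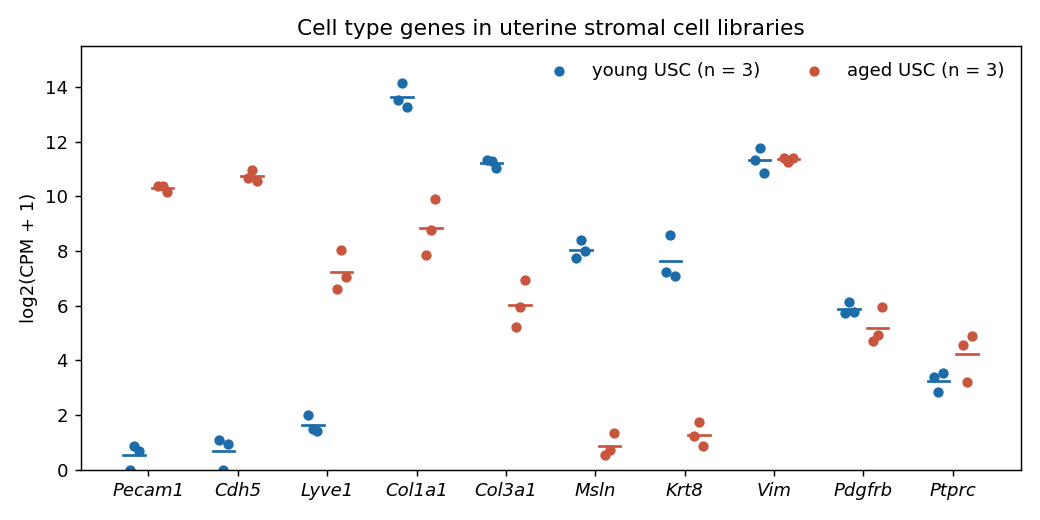
Expression of 10 marker genes in the 6 USC libraries, as log2(CPM + 1) on the vertical axis, with each point a library and each short line a group mean (3 young, 3 aged). Pecam1 lies at or below 0.826 CPM in all young libraries and at or above 1134 CPM in all aged ones, whereas Vim has mean values of 2622 and 2630 CPM; the genes were chosen after their values were seen.

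Extracellular matrix genes fell in 24 of 37 tested members and rose in 4 (26 and 4 when adjusted over the list alone), median log2 change −2.12. Camera's adjusted p of 1.10e-07 was lost with an estimated correlation (adjusted p = 0.207). Col1a2, a chain of fibrillar collagen, fell from 3864 ± 351 to 91.9 ± 4.46 CPM (log2 change −5.39, SE 0.31). The small proteoglycan genes Ogn and Lum fell from 323 ± 168 to 3.44 ± 1.54 CPM and from 12.8 ± 5.08 to 0.192 ± 0.0348. Mmp13, a collagenase, rose from 2.21 ± 0.728 to 60.8 ± 22.4 CPM, and the collagen genes Col14a1 and Col15a1 rose from 5.44 ± 0.857 to 65.4 ± 46.7 and from 2.47 ± 0.623 to 26.4 ± 11.7. The log2 change of Col14a1 was 3.58, and 2.83 without aged replicate 3. Mesothelial markers fell in 7 of 9 tested members and rose in 1 (7 and 1 when adjusted over the list alone), median −6.14. In camera the adjusted p was 2.02e-05, with adjusted p = 0.136 at an estimated correlation. Msln, the mesothelial surface protein, fell from 267 ± 62.2 to 0.880 ± 0.568 CPM and Upk3b from 225 ± 19.6 to 1.35 ± 0.665, while Gpm6a rose from 2.63 ± 2.01 to 57.4 ± 9.54 (log2 change 4.39, and 5.15 without young replicate 1). Cd34, which endothelial cells express, was 2.302 ± 0.563 CPM in young and 724 ± 103 in aged USC.

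Wnt signalling genes fell in 16 of 21 tested members and rose in 1 (17 and 2 when adjusted over the list alone), median log2 change −2.39. The list's adjusted p in camera was 9.83e-07, and adjusted p = 0.170 with an estimated correlation. Rspo1, an enhancer of Wnt signalling, had 2394 counts in young and 2 in aged libraries, a ratio of 1352 (374 to 11170, 95% counting interval). The Wnt antagonist genes Nkd1 and Sfrp2 fell from 24.1 ± 2.33 to 0.326 ± 0.269 CPM and from 33.4 ± 5.88 to 0.967 ± 0.614, while Sfrp1, another antagonist, rose from 158 ± 81.7 to 555 ± 82.0. The log2 change of Nkd1 was −6.24, and −6.93 without aged replicate 3, and that of Sfrp2 −5.09, and −5.71 without aged replicate 2. Developmental transcription factors outside the Hox clusters fell in 19 of 33 tested members and rose in 6 (20 and 7 when adjusted over the list alone), median −2.94. Camera's adjusted p was 0.000306, and adjusted p = 0.207 with an estimated correlation. Wt1, a regulator of mesothelium and urogenital development, fell from 245 ± 83.0 to 6.44 ± 0.929 CPM and Bhlhe22 from 47.4 ± 11.9 to 1.18 ± 0.369, while Foxc2, a factor of vascular and lymphatic development, rose from 1.27 ± 0.853 to 56.9 ± 2.07. Hox genes went both ways, 11 rising and 12 falling of 32 tested (11 and 13 when adjusted over the list alone), and camera did not pass (adjusted p = 0.185). Hoxb9 rose from 0.683 ± 0.449 to 14.1 ± 4.46 CPM and Hoxd8 from 18.7 ± 2.82 to 62.6 ± 4.18, whereas Hoxd11 fell from 112 ± 16.3 to 4.50 ± 1.49 and Hoxc6 from 43.2 ± 4.90 to 1.15 ± 0.271. The endothelial gene Robo4 moved from 0.105 to 246 CPM in these libraries.

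Decidualisation and progesterone response genes fell in 12 of 34 tested members and rose in 6 (15 and 7 when adjusted over the list alone), median log2 change −0.34. Camera did not pass (adjusted p = 0.213), although without young replicate 2 its adjusted p was 0.0459. Hand2, a transcription factor downstream of progesterone in stroma, fell from 182 ± 60.2 to 4.55 ± 0.341 CPM (log2 change −5.32, SE 0.35, edgeR adjusted p 9.85e-06). Esr1, the estrogen receptor, fell from 71.8 ± 25.6 to 8.12 ± 0.916 CPM (−3.14, SE 0.35, edgeR adjusted p 0.000139). Pgr, the progesterone receptor, fell from 53.0 ± 56.2 to 2.55 ± 1.33 CPM (−4.36, SE 0.79, edgeR adjusted p 0.00251). Its log2 change was −2.96 without young replicate 3, the library with the most Pgr counts (edgeR adjusted p 0.00447). Hoxa11 fell from 46.0 ± 11.51 to 2.74 ± 0.855 CPM, Hoxa10 from 50.6 ± 15.6 to 6.95 ± 0.885 and Wnt4 from 72.5 ± 43.9 to 4.73 ± 2.40, all regulators of the implantation uterus. Bmp2, an inducer of decidualisation, was too low to test at 0.955 ± 0.338 and 0.271 ± 0.256 CPM. Epas1, an oxygen-sensitive transcription factor abundant in endothelium, rose from 8.70 ± 1.99 to 266 ± 7.24 CPM, Lifr from 7.06 ± 4.64 to 85.1 ± 3.05 and Hsd11b1, a glucocorticoid-activating enzyme, from 0.141 ± 0.154 to 5.34 ± 1.35. The log2 change of Wnt4 was −3.95, and −3.32 without young replicate 2. That of Lifr was 3.59, and 4.26 without young replicate 3. That of Hsd11b1 was 5.28, with 4.55 and 6.62 without young replicates 1 and 3. Pecam1 stood at 1134 to 1321 CPM in the aged libraries.

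Among the DNA methylation genes 3 of 18 tested members rose and 2 fell (3 and 2 when adjusted over the list alone), and camera did not pass (adjusted p = 0.383). Dnmt1, the maintenance methyltransferase, rose from 81.3 ± 18.6 to 172 ± 22.5 CPM (log2 change 1.08, SE 0.27, edgeR adjusted p 0.0151). That call was lost without aged replicate 1 (1.04) or aged replicate 2 (1.02), as was that of its partner Uhrf1 (main value 1.07; 1.04 and 0.98). Mbd1, a methyl-CpG binding gene, fell from 80.7 ± 11.6 to 35.8 ± 1.17 CPM and Gadd45b from 111 ± 47.8 to 22.4 ± 3.67. The de novo enzyme gene Dnmt3a (89.5 ± 49.1 and 51.3 ± 4.41 CPM) had an edgeR adjusted p of 0.155. Dnmt3b (1.34 ± 0.583 and 2.18 ± 0.721 CPM) had 0.365. The demethylation genes Tet2 (32.3 ± 15.7 and 25.2 ± 3.19 CPM) and Tet3 (73.9 ± 36.8 and 54.9 ± 8.09 CPM) had 0.555 and 0.449. Without young replicate 2, Dnmt3a (log2 change −1.08), Tet2 (−0.70) and Tet3 (−0.73) passed. Tet1 was too low to test, at 0.557 ± 0.846 and 0.309 ± 0.0903 CPM. Polycomb genes rose in 2 of 26 tested members and fell in 1 (2 and 1 when adjusted over the list alone; camera adjusted p = 0.449). Cbx7 rose from 3.66 ± 1.05 to 14.9 ± 1.57 CPM and Phf19 from 4.69 ± 1.56 to 16.5 ± 1.81. Flt4, a receptor of lymphatic endothelium, stood at 0.764 ± 0.233 CPM in the young and 523 ± 146 in the aged libraries.

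Imprinted genes fell in 12 of 31 tested members and rose in 2 (15 and 3 when adjusted over the list alone), median log2 change −0.85. In camera the adjusted p was 0.00433, and adjusted p = 0.136 with an estimated correlation. Meg3, a maternally expressed non-coding RNA, fell from 371 ± 53.8 to 27.8 ± 3.48 CPM, and its neighbour Dlk1 from 10.8 ± 3.76 to 0.280 ± 0.308 (log2 change −5.34, with −4.69 and −6.45 without aged replicates 2 and 3). Zdbf2 had 504 counts in young and 2 in aged libraries, a ratio of 285 (78.4 to 2357, 95% counting interval). Mest, which is expressed from the paternal allele, rose from 1.22 ± 0.582 to 244 ± 28.4 CPM. Proliferation genes rose in 12 of 30 tested members (17 when adjusted over the list alone), median 0.78. The list's adjusted p in camera was 2.48e-05, and adjusted p = 0.420 with an estimated correlation. Mcm5, of the replicative helicase, rose from 44.4 ± 10.8 to 123 ± 12.6 CPM, and Cenpf, a kinetochore protein, from 35.7 ± 6.21 to 92.8 ± 20.7. The endothelial gene Cdh5 stood at 1513 to 2009 CPM in the aged libraries.

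TGF-beta and BMP genes fell in 11 of 27 tested members and rose in 4 (11 and 4 when adjusted over the list alone; camera adjusted p = 0.185). The growth factor gene Bmp6 rose from 9.37 ± 3.09 to 149 ± 13.4 CPM and Fst, an activin antagonist, from 29.0 ± 4.33 to 475 ± 158, while Tgfb3 fell from 510 ± 62.6 to 63.7 ± 11.1. Senescence and secretory genes rose in 10 of 27 tested members and fell in 7 (10 and 7 when adjusted over the list alone; camera adjusted p = 0.309). The stress-induced Gdf15 rose from 0.264 ± 0.0781 to 20.5 ± 6.12 CPM and the chemokine gene Ccl2 from 58.0 ± 18.1 to 588 ± 52.1. Igfbp3, an insulin-like growth factor binding protein, fell from 396 ± 99.6 to 7.41 ± 1.61. Hypoxia and glycolysis genes rose in 6 of 23 and fell in 2 (7 and 5 when adjusted over the list alone). Their median was −0.33 although camera's direction was up (adjusted p = 0.748). Adm, a vasoactive peptide gene, rose from 16.5 ± 3.72 to 542 ± 32.2 CPM, and Vegfa, a growth factor for blood vessels, fell from 103 ± 26.8 to 20.6 ± 9.93. Immediate early and heat shock genes rose in 3 of 22 and fell in 6 (3 and 8 when adjusted over the list alone; camera adjusted p = 0.309), with Atf3 rising from 2.19 ± 0.871 to 14.7 ± 0.958 CPM and Egr1 falling from 218 ± 64.5 to 60.9 ± 19.4. Cholesterol biosynthesis genes rose in 3 of 23 and fell in 3 (3 and 4 when adjusted over the list alone; camera adjusted p = 0.932). Pcsk9, which lowers surface LDL receptors, had 0 counts in all aged libraries, at least 47.8-fold lower than in young. Pecam1 lay at or below 0.826 CPM in the young libraries and at or above 1134 in the aged.

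Epithelial markers rose in 3 of 10 tested members and fell in 2 (3 and 3 when adjusted over the list alone). Their median was −0.17 although camera's direction was up (adjusted p = 0.588). The keratin genes Krt8 and Krt7 fell from 224 ± 141 to 1.51 ± 0.770 CPM and from 123 ± 68.4 to 0.417 ± 0.103. The log2 change of Krt8 was −7.18, and −6.50 without young replicate 2. Prom1 rose from 0.126 ± 0.119 to 127 ± 23.5 CPM, and the secreted protein genes Lcn2 and Wfdc2 were at least 450-fold and 34.8-fold higher in aged USC. Macrophage markers rose in 1 and fell in 1 of 20 (1 and 1 when adjusted over the list alone; camera adjusted p = 0.748), with the mannose receptor Mrc1 rising from 8.15 ± 0.600 to 40.4 ± 20.8 CPM and the chemokine receptor Cx3cr1 falling from 13.3 ± 1.47 to 1.64 ± 0.359. Lists with fewer than 3 tested members were not given to camera. Of these, 1 lymphoid gene was tested and rose (Ccl5, 0.157 ± 0.273 to 4.50 ± 0.424 CPM), 1 of 2 germline genes fell (Tex15, 1.62 ± 0.552 to 0.259 ± 0.181) and 1 of 2 trophoblast genes rose (Prl2c2, at least 30.1-fold), with the same counts when adjusted over the list alone. The log2 change of Ccl5 was 5.00, with 4.27 and 8.78 without young replicates 1 and 2. That of Tex15 was −2.54, and −3.18 without aged replicate 1. The Tex15 call was lost without aged replicate 2 (log2 change −2.41) or aged replicate 3 (−2.22). None of 2 erythroid genes passed in edgeR (0 at an unadjusted p under 0.05, and 0 in DESeq2). None of 11 mitochondrially encoded transcripts passed in edgeR (0 when adjusted over the list alone, 3 at an unadjusted p under 0.05, and 0 of 13 in DESeq2), median −0.70, camera adjusted p = 0.347. The endothelial gene Robo4 stood at 0.105 and 246 CPM in these libraries.

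**Figure D2:**
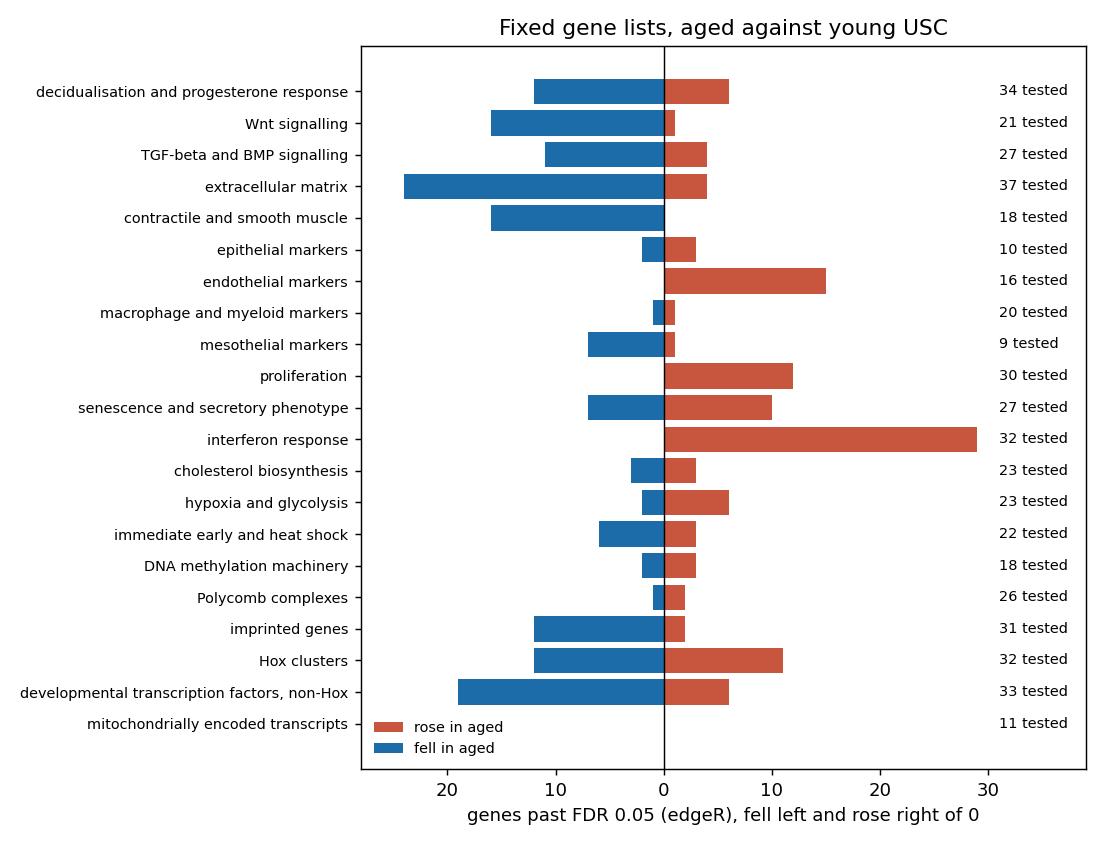
Number of genes per list that fell (left) or rose (right) in aged against young USC at an FDR of 0.05 in edgeR (3 libraries per age), with 1 pair of bars per list. Endothelial markers have 15 of 16 tested genes rising and interferon response genes 29 of 32, while 16 of 18 contractile genes fell.

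The largest rises included Gimap6 (ENSMUSG00000047867, chromosome 6, 48701582 to 48708225), a GTPase gene of the immunity-associated family, with 0 counts in young and 216 ± 24.7 CPM in aged USC, at least 2354-fold higher. Sox7, a transcription factor of vascular development, was at least 1052-fold higher at 96.6 ± 11.9 CPM, and Kit, the stem cell factor receptor, at least 643-fold higher at 57.9 ± 19.4. The sodium channel genes Scn3a and Scn5a were at least 1120-fold and 865-fold higher, and the transcription factor gene Tbx1 at least 702-fold. Mmrn2, an endothelial matrix gene, had 3 counts in young and 25843 in aged libraries, a ratio of 7627 (2610 to 36988, 95% counting interval). Plvap, a component of endothelial fenestrae, went from 0.259 ± 0.239 to 1220 ± 152 CPM (log2 change 12.34, with 11.59 and 13.14 without young replicates 1 and 2). The largest falls included Casq2 (ENSMUSG00000027861, chromosome 3, 102086415 to 102146514), a calcium-binding protein of the sarcoplasmic reticulum, at 20.96 ± 1.30 CPM in young and 0 counts in aged USC, at least 259-fold lower. Cpxm2 was at least 233-fold lower, Nell2 213-fold, D3Bwg0562e 168-fold, Il17re 163-fold and the ephrin receptor gene Epha3 161-fold. Agtr1a, an angiotensin receptor gene, had 2281 counts in young and 2 in aged libraries, a ratio of 1288 (356 to 10643). S100g, a calcium-binding protein gene, had 1093 counts against 1, a ratio of 1234 (221 to 48802), and 1500015O10Rik 2039 against 1, a ratio of 2303 (413 to 91003). How the stromal cells were isolated is not given in the sources used here. In simulated libraries of this depth, with 50 genes changed at each fold, 18% of 2-fold and 82% of 4-fold changes were recovered. Far fewer genes were changed there than the 3382 that passed in the real libraries. The adjusted threshold is stricter with fewer changes, so these shares do not measure the power of the real comparison.

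The uterus comparison asked whether CpG islands differ in MeDIP signal between aged and young females at E3.5. A few islands passed as gains with age, most of them with few reads. The largest gains were in a coding exon of the hair keratin gene Krt87 and a non-coding exon of Gm29683. Of 6814 tested islands, 6 passed an FDR of 0.05 in limma, all gains, with 507 at an unadjusted p under 0.05. On recovered reads edgeR passed 20, of which 19 were gains, and 5 passed both tools. The Krt87 island (chromosome 15, 101438262 to 101439276) went from 1.07 ± 0.97 (SD, n = 3) to 3.99 ± 0.28 (n = 5) on the log2 scale, a change of 2.92 (SE 0.56, limma adjusted p 0.0303). The Gm29683 island (chromosome 7, 70337416 to 70338298) changed by 2.91 (SE 0.56, limma adjusted p 0.0303), and by 3.60 without young replicate 3. Coding exons of Atp2a3, a calcium pump of the endoplasmic reticulum (chromosome 11, 72960658 to 72962002), and of Fbrsl1 (chromosome 5, 110362803 to 110363993) gained 2.14 and 1.87. That of Tnfrsf25, a death domain receptor (chromosome 4, 152119359 to 152120032), gained 2.28 in limma (3.02 without young replicate 1) but had an adjusted p of 0.162 in edgeR. An intergenic island on chromosome 6 (51592191 to 51593252), chosen after its values were seen, gained 2.19. Mean reads per library were 5.9 at Krt87, 6.05 at Gm29683, 6.65 at Tnfrsf25 and 7.2 at Atp2a3, near the minimum of 5 for testing. They were 10.6 at Fbrsl1 and 12.25 at the intergenic island. Islands of developmental transcription factors stood higher as a list (median log2 change 0.43 over 80 islands, against −0.02 over all islands). Camera's adjusted p was 3.21e-05, and adjusted p = 0.247 with an estimated correlation. Of the list's own islands 0 passed over all islands in limma, and 4 gains and 1 loss passed when adjusted over the list alone. The other lists did not pass camera (imprinted adjusted p = 0.865, germline 0.0549, Hox 0.348, decidualisation 0.245). The count was 12 (10 gains, 2 losses) with quantile normalization, and 0 without aged replicate 4 or 5. Among islands above the median of mean signal it was 0 too. It was 2 without young replicate 2 (0 of them among the 6 of the main run) and 3 without young replicate 3 (2 among the 6). It was 2 without aged replicate 1 (1 among the 6) or 3 (2 among the 6).

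Age was compared in decidua at E11.5 beside embryos of normal and of abnormal appearance, both against the same 3 young deciduae. No island passed in either comparison. For normal deciduae limma passed 0 islands with 473 at an unadjusted p under 0.05 and a smallest adjusted p of 0.232, and edgeR passed 0. For abnormal deciduae limma passed 0 with 407 at an unadjusted p under 0.05 and a smallest adjusted p of 0.737, and edgeR passed 0. The median over all islands was 0.23 and 0.21 higher in aged deciduae, and −0.01 and 0.00215 after quantile normalization, so the values named are to be read against that shift. The smallest p-values, none passing, were at coding exons of Six3 (chromosome 17, 85620653 to 85622431), a developmental transcription factor, and Gdf11 (chromosome 10, 128890613 to 128892478), a TGF-beta family ligand. The Six3 island had 0.75 ± 0.37 (n = 3) in young and 3.07 ± 0.23 (n = 5) in aged normal deciduae, limma adjusted p 0.232. The Gdf11 island had 0.10 ± 0.64 in young, 2.41 ± 0.90 in aged normal and 2.302 ± 0.60 (n = 4) in aged abnormal deciduae, limma adjusted p 0.232 and 0.737. It passed in normal deciduae without aged normal replicate 4 (2.69). Further islands among the smallest p-values were those of Cnmd (1.57), Eno2 and Lrrc23 (−1.74), Thbd (−1.49) and Rhof (−1.37) in normal deciduae. In abnormal deciduae they were those of Zmat1 (1.92), Exoc3l2 (1.50), Tcte1 (−1.34), Rnf165 (−0.91) and Tmem91 (−1.42). The lists did not pass camera in either (smallest adjusted p 0.292 and 0.277, both germline genes). In simulated data 72% and 52% of 4-fold changes were recovered. Single islands passed without young replicate 2 (1) or aged normal replicate 4 (1) in the first comparison, and without abnormal replicate 2 (1) in the second.

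The abnormal and normal deciduae of aged mothers were compared to ask whether the embryo's appearance goes with a difference in the decidua. No island passed. limma passed 0 with 157 at an unadjusted p under 0.05 and a smallest adjusted p of 0.736, edgeR passed 0, and limma with the litter as a block passed 0. The smallest p-values, none passing, were at an untranslated region shared by Eno2, a glycolytic enzyme gene of neurons, and Lrrc23 (chromosome 6, 124768658 to 124770091), and at an intron of Tcte1 (chromosome 17, 45530399 to 45530766). The first had 0.38 ± 0.65 (n = 5) in normal and 2.12 ± 0.37 (n = 4) in abnormal deciduae, and the other 4.73 ± 0.31 and 3.13 ± 1.04, each with a limma adjusted p of 0.736. Islands of Mnx1 (1.80) and Sox1ot (1.39), and of Gm20388 (−1.70) and Adam23 (−1.55), followed. No list passed camera (adjusted p 0.884 to 0.919). In simulated data 32% of 2-fold and 84% of 4-fold changes were recovered, and 1 island passed without abnormal replicate 2.

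Decidua at E11.5 was compared with uterus at E3.5 to ask how island methylation differs between these stages, which also differ in tissue. In young females few islands differed. The clearest gain was in an intron of Cdkl4, a kinase gene, and the only loss was in an intron of Ccnd3, a cyclin gene. Of 6814 tested islands, 7 passed in limma (6 gains, 1 loss), with 872 at an unadjusted p under 0.05. On recovered reads edgeR passed 104 (66 gains, 38 losses), and all 7 passed both tools. The Cdkl4 island (chromosome 17, 80550176 to 80550628) stood at 4.00 ± 0.59 in uterus and 6.91 ± 0.52 in decidua (n = 3 each), a change of 2.90 (SE 0.49, limma adjusted p 0.00999). The Ccnd3 island (chromosome 17, 47523180 to 47523574) lost 2.35 on the log2 scale, a value of −2.35 (SE 0.50, limma adjusted p 0.0462), and −2.99 without young decidua replicate 1. Gains of 2.70, 1.79 and 1.57 passed at Zfp180 (chromosome 7, 24081586 to 24082594, untranslated region), Gm32635 (chromosome 12, 106094781 to 106095185, non-coding exon) and Gm13658 (chromosome 2, 75434587 to 75435274, upstream). The Zfp180 value was 1.89 and no longer passed without young uterus replicate 2 (limma adjusted p 0.157), and was 3.39 without young uterus replicate 3. Intergenic islands on chromosome 6 (73429433 to 73430169) and chromosome 13 (65309923 to 65310307), chosen after their values were seen, gained 3.16 and 2.00. No list passed camera (smallest adjusted p 0.110, developmental transcription factors). Quantile normalization gave 48 (28 gains, 20 losses), and the count was 0 without young decidua replicate 2 or 3 or young uterus replicate 2. It was 28 without young uterus replicate 1, and 4 without young decidua replicate 1 or young uterus replicate 3.

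In aged females many islands differed between uterus and normal decidua. The largest gain in decidua was in an intron of Il20rb, a cytokine receptor gene, and the largest loss in an exon of Wnt7b, a Wnt ligand gene. Of 80 islands of developmental transcription factors outside the Hox clusters 8 lost and 5 gained, and the list did not pass camera with an estimated correlation (adjusted p = 0.153). limma passed 1259 of 6814 islands, 1103 gains and 156 losses. Quantile normalization gave 719 (410 gains, 309 losses), and edgeR on recovered reads 1113 (652 gains, 461 losses), of which 800 were shared with limma. The median over all islands was 0.32 higher in decidua as deposited and −0.000512 after quantile normalization. The Il20rb island (chromosome 9, 100463308 to 100463813) went from 1.40 ± 0.43 to 5.19 ± 0.50 (n = 5 each), a change of 3.80 (SE 0.41, limma adjusted p 8.25e-07). The Wnt7b island (chromosome 15, 85576120 to 85578453) went from 4.04 ± 0.45 to 0.28 ± 0.75, a change of −3.76 (SE 0.44, limma adjusted p 2.68e-06). The next gains were 2.95 at Epb41l5, a cytoskeletal adaptor, 2.71 at Tor4a, 2.69 at the apoptosis gene Hrk, 2.64 at Msrb3 and 2.63 at the protocadherin gene Pcdhb22. The next losses were −3.44 at the amino acid transporter gene Slc36a4, −3.24 at 2810410L24Rik, −2.93 at Eno2 and Lrrc23, −2.48 at the homeobox gene Emx1 and −2.39 at Sox1ot.

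By list, 13 of 36 Hox islands gained and 1 lost (15 and 1 when adjusted over the list alone), with a median of 0.55. In camera the adjusted p was 0.0406, and adjusted p = 0.823 with an estimated correlation. Exons of Hoxb3 (chromosome 11, 96343951 to 96344715 and 96345267 to 96346476) gained 1.72 and 1.97, and Hoxb4 gained 2.00. The Hoxa11 island (chromosome 6, 52244754 to 52246872) lost signal with −1.85, a call lost without aged normal decidua replicate 4 (−1.59) or aged uterus replicate 3 (−1.67). Developmental transcription factors gained in 5 and lost in 8 of 80 islands (5 and 8 when adjusted over the list alone), median −0.16. The list's adjusted p in camera was 2.38e-06, and adjusted p = 0.153 with an estimated correlation. The kidney and reproductive tract regulator Pax2 lost with −2.24 and Barx2 with −1.96. Germline genes gained in 9 and lost in 1 of 28 islands (9 and 1 when adjusted over the list alone), median 0.58, camera adjusted p = 0.0406, and adjusted p = 0.823 with an estimated correlation. The island of Sycp3, of the synaptonemal complex, gained 1.35 and that of the cohesin gene Stag3 lost with −1.45, a call lost without aged normal decidua replicate 5 (−1.16). Imprinted genes gained in 6 and lost in 1 of 51 islands (5 and 1 when adjusted over the list alone; camera adjusted p = 0.548), with Impact (chromosome 18, 12972727 to 12974731) gaining 2.01 and Magel2 losing with −1.89. Decidualisation genes gained in 5 and lost in 1 of 17 islands (5 and 1 when adjusted over the list alone; camera adjusted p = 0.788), with Wnt4 gaining 1.51 and the corepressor gene Ncor2 1.48. Among genes of the other lists the Wnt effector Tcf7l2 gained 1.64, Wnt6 1.72, the tight junction gene Cldn4 1.65 and the trophoblast gene Plet1 1.93, and the receptor gene Fzd2 lost with −1.59. After quantile normalization 14 named islands lost their call, all of them in this comparison. Among them, islands of Cdh5 (1.12), Col6a2 (1.07) and Tnc (0.86) gained as deposited but did not pass after it (0.61, 0.54 and 0.22). On recovered reads in edgeR 13 named islands lost their call, counted over all comparisons. Leaving out aged uterus replicate 3 gave 837 islands.

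**Figure D3:**
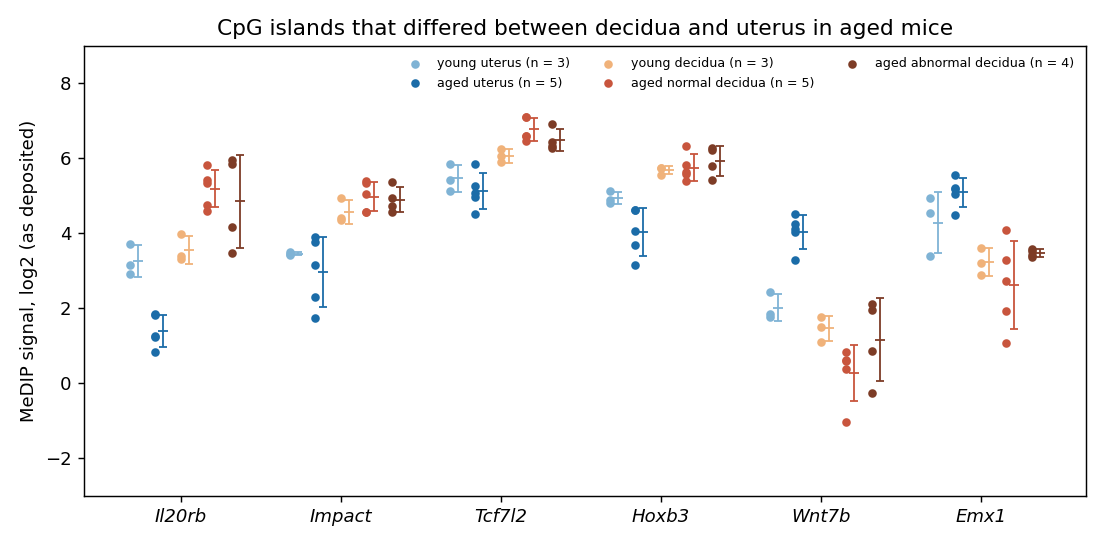
MeDIP signal of 6 CpG islands (log2 of scaled reads per kb) in young and aged uterus and decidua, with each point a library and bars showing mean ± SD (3 to 5 libraries per group). The Il20rb island has means of 1.40 in aged uterus and 5.19 in aged normal decidua, and the Wnt7b island 4.04 and 0.28; the islands were chosen after their values were seen.

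Whether the stage difference itself differs with age was tested as an interaction. limma passed 0 islands with 477 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0697, and edgeR passed 2 (1 in each direction). The smallest p-values were at Il20rb (3.499), the calmodulin-like gene Calml3 (1.96; chromosome 13, 3803689 to 3804130) and Six3 (3.10), and at Rhof (−2.96), Eno2 and Lrrc23 (−2.84) and Wnt7b (−3.21). Of these Calml3 and Wnt7b passed in edgeR, with an adjusted p of 0.0376 each. The Il20rb island stood at 3.27 ± 0.42 in uterus and 3.56 ± 0.37 in decidua of young females (n = 3 each). Camera passed for germline genes (median 0.53 over 28 islands, adjusted p = 0.00697) and for developmental transcription factors (median −0.15 over 80 islands, adjusted p = 0.00564). Both were lost with an estimated correlation (adjusted p = 0.694 each). In simulated data 24% of 4-fold and 66% of 8-fold interactions were recovered. The count was 4 without aged uterus replicate 1, where Il20rb (3.46), Calml3 (2.01) and Six3 (3.48) passed, and 1 without young decidua replicate 2.

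The authors also deposited genome windows selected for a difference between E3.5 uterus and E11.5 decidua, 1 list per age. Nearly all windows in both lists gained signal in decidua, mostly in introns and between genes. The young list held 3802 windows, 3799 gains with a mean of 2.38 ± 0.51 (SD over windows) and 3 losses. The aged list held 4124 windows, 4115 gains with a mean of 2.10 ± 0.43 and 9 losses. Windows had a median length of 200 bp. Introns held 49.4% of young and 49.6% of aged windows, and 45.6% and 44.1% were intergenic, while 0.947% and 1.87% lay in CpG islands. A CA/TG tract lay in or within 200 bp of 64.8% and 71.2%, against 8.03% of random windows of the same lengths. Uterus and decidua libraries did not overlap in 99.8% of young and 57.3% of aged windows, but the windows had been selected on these same libraries, so this is no independent evidence. The authors' selection rule and p-values are not given in the sources used here.

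Introns of hormone response genes were among the gaining windows. An intron of Esr1 (chromosome 10, 4965401 to 4965600) gained in both lists, from 2.81 ± 0.93 to 5.83 ± 0.12 in young (n = 3 each) and from 2.61 ± 1.14 (n = 5) to 5.07 ± 1.05 (n = 9) in aged. In the window values for aged decidua these 9 libraries are 5 normal and 4 abnormal deciduae of 5 litters, of which 4 gave 2 libraries each, so they are not 9 independent animals. An intron of Fkbp5, a progesterone-induced chaperone (chromosome 17, 28509201 to 28509600), gained 2.51 and 1.88, and an intron of Hsd11b1 (chromosome 1, 193255801 to 193256000) 2.36 and 2.31. The decidualisation list had 11 windows in 5 genes in young and 9 in 7 genes in aged, imprinted genes 7 in 6 and 13 in 9, and extracellular matrix genes 9 in 7 and 12 in 8. An intron of the imprinted non-coding RNA gene Rian gained 3.08 in young and 2.38 in aged, one of the collagen gene Col8a1 2.55 and 3.27, one of the co-receptor gene Tgfbr3 2.77 and 2.38, and one of the demethylation gene Tet2 2.27 and 1.91. A coding exon of Dnmt1 (chromosome 9, 20942401 to 20942600) gained 2.00 and 2.16. The largest gains among protein-coding genes were 4.06 at Dnajc6, 4.02 at T2 and 3.98 at Gsg1l in young, and 3.499 at Syne2, 3.496 at Golga7b and 3.42 at 4932438A13Rik in aged, all in introns. Of the losses, 2 of 3 in young and 8 of 9 in aged lay in Sfi1 on chromosome 11, a centrosomal protein gene. The largest was −2.60 (chromosome 11, 3140201 to 3140400, coding exon), in aged decidua.

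The lists were overlapped to ask whether the same places differ with stage at both ages. Of the young windows 1951 (51.3%) shared at least 1 bp with an aged window, all with the same sign, and 1266 were identical. Shuffled positions gave a mean of 3.80 and at most 10 shared windows (permutation p 0.000999, the smallest that 1000 shuffles can give). With the windows near CA/TG tracts placed on such tracts, they gave a mean of 38.6 and at most 59. Both placements drew the other windows from whole chromosomes, not from places the assay can cover. Of random windows 21.9% held no CpG, against 0.132% of young and 0.097% of aged windows. An excess over the shuffles can therefore arise from shared coverage alone. Over the 1266 identical windows the mean log2 signal was 5.04 ± 0.25 in young decidua (n = 3), 4.90 ± 1.02 in aged normal (n = 5) and 4.59 ± 0.65 in aged abnormal decidua (n = 4). It was 2.66 ± 0.14 in young (n = 3) and 2.59 ± 0.40 in aged uterus (n = 5). No difference with age passed an exact permutation test (2-sided p 0.875 for normal decidua, 0.371 for abnormal decidua and 0.821 for uterus), nor did abnormal against normal decidua (exact p 0.643). The smallest p that these designs allow are 0.0179, 0.0286, 0.0179 and 0.00794. These are 4 unadjusted tests. Paired by litter, abnormal stood below normal decidua in 4 of 4 litters, with a mean difference of −0.50 ± 0.51 (SD, n = 4 pairs). The exact sign-flip p was 0.125, 2-sided, the smallest that 4 pairs can give. The differences were −0.26, −0.15, −0.36 and −1.26 in litters 2 to 5, so litter 5 carried much of the mean. The paired test was chosen after seeing the data. The aged normal deciduae spread widely, from 4.14 to 6.46, with replicates 4 and 5 at 5.45 and 6.46, and abnormal deciduae of the same litters at 5.09 and 5.20.

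**Figure D4:**
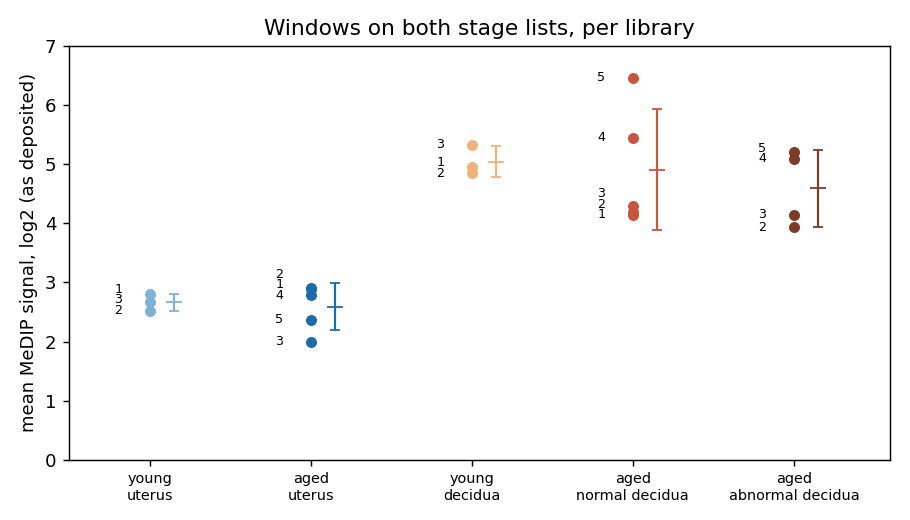
Mean MeDIP signal (log2 of scaled reads per window) over the 1266 windows on both lists, with each point a library marked by its replicate number and bars showing mean ± SD, in 5 groups of 3 to 5 libraries. Uterus libraries lie between 1.99 and 2.91 and decidua libraries between 3.93 and 6.46; the windows were selected by the authors on these libraries.

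The window lists were joined to USC expression to ask whether genes with a gaining window differ in expression with age. Of the genes with a gaining window in young, 754 were tested, of which 158 rose and 202 fell in aged USC (176 and 216 when adjusted over the list alone). Of those in aged, 877 were tested, 193 rising and 217 falling (215 and 233 when adjusted over the list alone). Camera passed 0 of 3 sets (limma, adjusted p = 0.951 for each, unadjusted p 0.671, 0.951 and 0.874, and adjusted p = 0.980 with an estimated correlation). The median log2 change was −0.06 for the young and −0.04 for the aged set, against −0.06 for all tested genes. Random sets of matched gene length had medians of 0.06 and 0.05, and 0.1% and 0.6% of 1000 such sets lay below the observed values, a comparison chosen after seeing the data. The share of changed genes was 47.7% and 46.8%, against 26.3% of all tested genes, but these genes are longer, with a median length of 107 and 98.2 kb against 23.3 kb, and no test of the share at matched length was made. Of the genes with a losing window, 2 in young and 3 in aged were tested and none passed in edgeR. Esr1 and Hsd11b1, which carried gaining windows, fell from 71.8 to 8.12 CPM and rose from 0.141 to 5.34 CPM. In the same libraries Pecam1 stood at or below 0.826 CPM in young and at or above 1134 in aged USC.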

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

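Of the tests in this part, those on cell type markers, exchanged libraries, CpG number, windows without a tract, group size and other splits of the samples were chosen after the result was seen; the tests on islands near CA/TG tracts and on rescaled subsets were written before their results.

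Aged USC libraries held endothelial genes at high levels and most stromal identity genes at lower levels than young USC. An exchange of single libraries between the ages is argued against by Pecam1, which reached at most 0.826 CPM in any young library and at least 1134 in every aged one. Stromal cells that kept their identity and gained endothelial transcripts are argued against for most of the stromal identity genes tested. Of 17 tested, 13 fell (Col1a1 from 13264 to 541 CPM, Col3a1 from 2395 to 73.3) and 2 rose (Dcn and Thy1). Their median log2 change was −4.07 (quartiles −5.32 to −2.59). All 17 had a mean above 1 CPM in young USC, and 14 of them still did in aged USC. The list was written after the USC result was seen, and 10 of its genes are in the fixed lists too, so these give no independent support. Outside the fixed lists Tcf21 (−7.28), Fap (−5.35), Mfap5 (−2.97) and Pdgfra (−2.59) fell, Thy1 rose, and Vim and Pdgfrb did not pass. Endothelial cells in the aged cultures are a candidate source: of 15 further endothelial genes, none in the fixed lists, 14 rose with a median of 8.27 (quartiles 6.69 to 9.13; Cd34 to 724 and Stab1 to 1492 CPM), 5 of the 15 were above 1 CPM in young USC, and no sort is described. All 5 tested lymphatic genes rose too (median 6.32; Lyve1 from 2.12 to 162 CPM), and an effect of age on the cells or wrong labels on a whole set of libraries stay open.

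Windows selected by the authors gained signal at E11.5 at both ages. Capture of uninterrupted CA/TG tracts of at least 16 bp that differs between library sets is argued against as the cause of the whole lists. Of gained windows, 29.3% in young and 24.2% in aged had no such tract within 500 bp. Interrupted tracts and other repeats were not counted there. Short tandem repeats lay in or within 200 bp of 71.2% of young and 76.0% of aged windows, against 19.3% of random windows. The median repeat share of windows was 85% and 78.5%, against 21.5%. Capture of other repeats was not tested. For part of the windows capture of CA/TG tracts is a candidate explanation, resting on the tested islands. These were not selected on a difference, but they were kept by their mean reads over all libraries. More of these libraries were decidua than uterus, so the minimum can favour islands high in decidua. Its share in the values below was not tested. Islands within 200 bp of a tract had a higher median decidua minus uterus difference than other islands, by 0.25 in young and 0.21 in aged. The permutation p was 0.0001 each, the smallest that 10000 permutations can give. The permutations shuffled islands, so this p does not measure spread between animals. In aged normal decidua replicates 1 to 3, medians were 3.77, 3.79 and 3.84 near a tract and 4.76, 4.77 and 4.77 away. In replicates 4 and 5 they were 4.48 and 4.14 against 5.07 and 4.32. The gap was narrower in these libraries, and the aged value leaned on them. Whether the gain follows the number of CpGs cannot be told apart, as the windows were selected on the difference itself (Spearman rho −0.15 in young and −0.000322 in aged). Over the tested islands away from tracts rho was −0.0484 and −0.138. A change in methylation at such repeats, between stages or between tissues, stays open and was not tested.

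More islands passed for stage in aged than in young females, 1259 against 7. Larger groups in the aged comparison are argued against as the whole cause, since 100 subsets of 3 against 3 aged libraries gave 163 to 1524 islands (median 538). Larger groups together with scaling are argued against likewise: after quantile normalization the subsets gave 94 to 507 islands, against 48 in young. The interaction passed 0 islands in limma (477 at an unadjusted p under 0.05) and 2 in edgeR, and an effect of age stays open.

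Other splits of the same libraries were counted for each model. For aged decidua against uterus 1 of 100 splits, the real one, gave as many as 1259 islands, and the highest other gave 233, so chance is excluded there. For aged against young uterus 5 of 56 splits gave at least 6 islands, so chance is not excluded. The highest other gave 69, several times the real count. It set young uterus replicates 1 and 3 and aged uterus replicates 1, 2 and 4 against the rest. The former had medians of 4.31 to 4.61 over tested islands, and the rest 3.82 to 4.26. Whether signal level accounts for that split was not tested. All 56 splits reached the real count of 0 for normal against young decidua (highest other 10), as did all 35 for abnormal against young decidua (1), and all 100 for the interaction (1). For abnormal against normal decidua all 100 did so, and the highest other, 17 islands, set litters 4 and 5 against the rest; with the litter as a block 0 islands passed. Splits of 3 against 3 number only 10, too few for a share under 0.05: in USC genes 1 split reached the real 3382 (highest other 0), in USC lists 6 reached 9 (11), in window gene sets 10 reached 0 (2), and in young decidua against uterus 1 reached 7 (0). For island lists chance is not excluded: 25 of 56 splits reached 1 list in uterus (highest other 3), 10 of 100 reached 3 in aged decidua against uterus (4), and 12 of 100 reached 2 in the interaction (3).

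Single libraries stood apart from the rest of their group in 16 of 337 groups of named islands and windows, where chance gives about 16.85 (1 in 20); 9 were in aged uterus, 6 of them in replicate 3. In aged uterus replicate 3 the island of Gm29683 stood at 2.93 on the log2 scale (others 4.18 to 4.51), that of Plagl1 at 2.96 (4.62 to 5.19) and that of Dpep3 at 4.72 (5.51 to 5.80), and windows in Fkbp5 at 2.43 (3.94 to 4.46), Mylk at 1.43 (3.20 to 3.32) and Il2rb at 1.43 (3 to 3.46). The window in Trappc9 stood at 2.87 in aged uterus replicate 4 (0 to 0.83). In aged uterus replicate 5 the Magel2 island stood at 3.45 (4.30 to 4.56) and the Rian window at 0.98 (3 to 3.68). In aged normal deciduae the Wnt7b island stood at −1.04 in replicate 2 (0.39 to 0.82), Slc36a4 at 2.16 in replicate 3 (−0.29 to 0.35), Col6a2 at 6.71 (6.10 to 6.26) and Plet1 at 4.56 (5.22 to 5.48) in replicate 4, and windows in Syne2 at 7.46 (5.42 to 5.77) and Sfi1 at 3.20 (3.71 to 3.85) in replicate 5. The Zmat1 island stood at 3.26 in abnormal decidua replicate 2 (3.94 to 3.98).

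The stage difference of islands differed between the ages for 2 gene lists in camera's interaction test, germline genes (adjusted p = 0.00697, up) and developmental transcription factors (adjusted p = 0.00564, down). Neither passed with an estimated correlation (adjusted p = 0.694 each).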

How the results depend on the processing

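The edgeR runs on recovered reads, the minimum of 10 reads, removal of the CpG density trend, the removal of litters 4 and 5, the aged subsets, the litter pairs over windows and the window lists reduced to their largest differences were chosen after seeing the data. No named result reversed. Of 117 tested named USC genes 101 kept their call in every alternative run, as did 13 of 21 USC lists and 47 of 87 named islands. Named windows were rerun only with 1 library left out. All 118 kept their direction, with a shift below the larger group SD. They are large differences selected on these same libraries, so this says little about how stable they are. Of 89 passing named USC genes with over 3 counts at each age, 18 moved by over 1.5 times in fold when 1 library was left out, as did 4 of 63 passing named islands. The cause of the changes below was not tested. Among islands with a mean of at least 5 reads per library, 52% to 84% of simulated 4-fold changes between groups were recovered, and 24% of 4-fold interactions. A stricter window list by smallest p was not run, as no p-values are held, and a pseudocount and other size factors had no place in log2 values.

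With an estimated correlation 2 USC lists and 0 island lists passed. Quantile normalization gave 12 islands in uterus, 48 in young stage, 719 in aged stage (against 1259) and 1 in the interaction. With no filter there were 2 in uterus, 0 of them shared with the 6 of the main run, and 0 in young stage. Among islands above the median of mean signal there were 0 and 1. Fits of only the compared groups gave 2 in uterus, 51 in young stage and 1 in the interaction. The edgeR counts were 20, 104 and 2 for these. A minimum of 10 reads gave 3, 29 and 2, and removing the CpG trend 3, 49 and 1. Without X and Y the young stage gave 13. Without litters 4 and 5 there were 2 for normal and 5 for abnormal against young decidua, 665 in aged stage and 1 in the interaction; subsets of 3 against 3 had a median of 538. Window lists reduced to their largest differences held 1901 and 2062 windows, 621 shared.

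With a replicate block there was 1 island in uterus, 7 in normal against young decidua, 28 in young stage and 1 in the interaction; 1011 passed in aged stage and 3340 genes in USC. These numbers do not pair the samples: correlations of same-numbered deviations ran from −0.11 to 0.37 in USC and from −0.08 to 0.06 in islands, and in no comparison did every sample correlate best with its own number. The litter block changed no call between abnormal and normal decidua. Over windows on both lists the difference was −0.31 between all libraries and −0.50 over the 4 litter pairs. This change comes from aged normal decidua replicate 1 (4.14), which has no pair and was left out, and not from the pairing. In the sign-flip test 4 pairs cannot give a p below 0.125.

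Leaving out 1 library gave 0 to 7 islands in uterus, 0 to 1 in each decidua comparison between ages and between abnormal and normal, 0 to 28 in young stage, 837 to 1405 in aged stage and 0 to 4 in the interaction, 2379 to 4486 USC genes, 9 to 10 USC lists, 4 to 7 island lists and 0 window gene sets.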

Other observations

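The values in this part were looked at after the main results were seen, and no explanation of them was tested.

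Among windows not described above, those in introns of the Wnt receptor genes Lgr5 (2.81) and Ror1 (2.46) stood higher in young decidua than in uterus, as did those of Flt1 (2.67), a receptor for vascular growth factors, and of the collagen gene Col5a1 (2.80). In aged decidua, windows in Ghr (2.84), the growth hormone receptor, in Egfr (2.298), the epidermal growth factor receptor, and in a coding exon of Il6st (2.17), a cytokine receptor subunit, stood higher. Imprinted loci included Usp29 (3.06) in the young and Gnas (2.56) in the aged list. Mesothelial, erythroid, proliferation, cholesterol and mitochondrial lists had 0 windows at either age. No test of single windows was run, since the authors selected them on the same libraries.

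In USC, Vim, an intermediate filament of mesenchymal cells, stood at 2622 CPM in young and 2630 in aged libraries (edgeR adjusted p 0.995), and Pdgfrb, a pericyte and fibroblast receptor, at 58.3 and 38.5 (edgeR adjusted p 0.263). Among stromal identity genes Thy1 rose from 296 to 1561 CPM and Dcn from 283 to 857, while Tcf21 fell from 99.2 to 0.621. Ramp2, which endothelium expresses, did not pass (174 and 94.6 CPM, edgeR adjusted p 0.126).

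The mean signal over windows on both lists separated aged litters 4 and 5 from the others in normal and in abnormal deciduae. Normal deciduae stood at 4.14, 4.19, 4.29, 5.45 and 6.46 for replicates 1 to 5, and abnormal deciduae at 3.93, 4.14, 5.09 and 5.20 for replicates 2 to 5. Among aged uteri replicate 3 had a median log2 value of 3.82 over tested islands, against 4.24 to 4.61 in the others.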
